A study of Mus musculus with 6 samples.

How the data were processed

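RNA sequencing was carried out on primary cultures of mouse nucleus pulposus cells, the cells of the soft core of the intervertebral disc. Per the labels' protocols, the tissue was dissected from mice of 8 weeks of age, digested with collagenase, and cultured to passage 2 in medium with fetal bovine serum, and total RNA passed a quality check before standard Illumina libraries were made. Every library is labelled male. The 6 libraries fall into 3 genotypes of Chsy3 with 2 libraries each, namely wild type, heterozygous and knockout. The series title speaks of a knockdown, whereas the sample labels give genotypes, and the genotypes were used here.

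The deposited table holds read counts for 46095 gene symbols in 6 columns, 1 per library, and each column was assigned to its library by the library's title. The counts are raw, as judged from the values, which are whole numbers with a different total in each column. The genome build GRCm38 and the program HISAT2 version 2.0.4 are named per the submitters' processing notes. The counting tool, the annotation release and the strand setting are not given in the sources used here. For that reason the reads of near-identical gene copies, of overlapping genes and of antisense partners may have been split or shared by the counting, and values of Ifi202b, Clca3a1, class I histocompatibility genes, the Oas and Ifit families, and ribosomal protein genes with many pseudogene copies are uncertain to that extent. The same holds for Xist, which overlaps an antisense gene. The table had 0 entries that name no gene.

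Total counts ranged from 29622117 to 33899611 per library. A count of 0 in a library allows a level of up to 3 counts, which is between 0.0880 and 0.104 CPM (counts scaled by library size). Such limits cover counting error only, since the reads carry no molecular identifiers.

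The counts were tested with edgeR version 4.0.16 under R version 4.3.3. Library sizes were scaled with TMM factors, which lay between 0.974 and 1.02. Genes with low counts were removed with the default filter by group, which left 16061 genes, and Chsy3 was kept in any case. All 6 libraries entered a single quasi-likelihood fit with robust estimation and 3 residual degrees of freedom, and each pair of genotypes was compared with a two-sided quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method over all tested genes of a comparison, with a threshold of 0.05. Log2 fold changes are given with their standard errors (SE), and CPM as the mean and standard deviation (SD) of the 2 libraries of a genotype. The labels do not say that the 2 libraries of a genotype came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

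A set of 39 gene lists covering extracellular matrix, signalling, metabolism, growth and markers of other cell types was fixed before the data were examined, as were the comparisons, the tests, the rule for naming genes and the alternative settings. The 37 lists with at least 5 tested members were compared with all other genes by camera (limma version 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera was repeated with a correlation estimated for each list. The match of the mitochondrially encoded genes to the symbols of the table was made after the table was seen. The lists of lymphocyte and neutrophil markers (0 of 17 members tested) and of erythroid markers (2 of 12 tested) were not tested.

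The genes named for a comparison were Chsy3 and genes from a selection made by rule. The selection held, among genes past the threshold with a mean of at least 3 log2 CPM, no overlap between the libraries of both groups and a symbol that is not a predicted or clone name, the 10 with the largest increase and the 10 with the largest decrease, or 5 of each for knockout against heterozygous. For each list described, the members named are among the 4 with the smallest p-values. Any collagen, proteoglycan, protease or chondroitin sulfate gene was also allowed as a member of its list. Positions are 1-based on GRCm38 and come from a match by symbol to the RefSeq gene table of that build, which placed 15642 of the 16061 tested genes.

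The procedure was tested on simulated counts made from the gene means over all 6 libraries and from their library sizes. In the knockout group 50 genes were changed at each of 4 sizes among 16061 genes, and a further list was shifted by 0.5 log2. Knockout was then compared with wild type. It called 18 of 50 genes changed 1.2-fold, 24 of 50 changed 1.5-fold, 41 of 50 changed 2-fold and 40 of 50 changed 4-fold, and 9 of 15836 unchanged genes. Chance agreement between the comparisons that share the wild-type libraries was estimated from 20 simulations with unchanged heterozygous and knockout groups.

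Alternative settings were RLE size factors, DESeq2 version 1.42.0, no filter and a stricter filter on low counts, the replicate number as a block, a fit of only the 4 libraries compared, robust estimation off, leaving out each library in turn, a 2-fold minimum for the change, and an estimated correlation in camera. Scaling by library totals alone and a fit without genes on the X and Y chromosomes were added after the data were seen.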

Results

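Gene expression was measured in nucleus pulposus cells at passage 2 from wild-type mice and from mice heterozygous or homozygous for a loss of Chsy3, with 2 libraries per genotype. Chsy3 encodes a chondroitin sulfate synthase, an enzyme that lengthens the sugar chains of proteoglycans such as aggrecan. Total counts were 33899611 and 33847284 in the wild-type libraries, 29622117 and 32524895 in the heterozygous libraries, and 32401764 and 33355685 in the knockout libraries. Reads fell in 19994 to 20422 genes per library. Libraries of the same genotype correlated at 0.987 to 0.989 across genes on the log2 CPM scale and libraries of different genotypes at 0.962 to 0.969. The first principal component held 42.5% of the variance and placed wild type on one side and heterozygous on the other, and the next held 33.2% and set the knockout apart from both.

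The cultures expressed genes of fibroblast-like and macrophage-like cells. Fn1 reached 15431 ± 127 CPM and Col1a1 10593 ± 168 CPM in wild type (SD, n = 2), and the macrophage genes Lyz2 and Csf1r reached 7211 ± 125 and 929 ± 0.272 CPM (SD, n = 2). Across the 6 libraries Lyz2 lay between 7010 and 8845 CPM and Spp1, which encodes osteopontin, between 9484 and 14400 CPM. The fat cell gene Adipoq lay between 0.265 and 2.25 CPM. Acan, which encodes aggrecan, had 8 counts in all libraries together, at most 0.235 CPM in a library, and the notochord gene T had 0. Both were thus close to absent, although every library held at least 29622117 counts. The name nucleus pulposus rests on the labels and not on these genes.

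Chsy3 (chromosome 18, 59175340 to 59411336, GRCm38) fell with the loss of its alleles. It had 284 and 284 counts in the wild-type libraries, 167 and 197 in the heterozygous libraries, and 118 and 76 in the knockout libraries, or 8.35 ± 0.0071, 5.99 ± 0.286 and 2.90 ± 0.956 CPM (SD, n = 2). The knockout mean was thus 34.8% and the heterozygous mean 71.8% of wild type. The log2 fold change was -1.53 ± 0.20 (SE) in knockout against wild type (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.59e-08), -0.48 ± 0.19 in heterozygous against wild type (edgeR, adjusted p = 0.0444) and -1.05 ± 0.21 in knockout against heterozygous (edgeR, adjusted p = 7e-05). The heterozygous decrease did not pass the threshold with DESeq2 (adjusted p = 0.119), nor in edgeR without wild-type library 1 or 2 (adjusted p = 0.111 and 0.108) or heterozygous library 1 or 2 (adjusted p = 0.181 and 0.0923), in a range of 0.0221 to 0.181 over 15 alternatives. The table counts reads over the whole gene, and the part of the gene that was altered is not given in the sources used here.

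Sex-linked genes went against the male label in every library and set the heterozygous libraries apart from the others. Ddx3y, Uty, Kdm5d and Eif2s3y, which lie on the Y chromosome, had 0 counts in both heterozygous libraries, against 24.4 ± 4.12, 8.06 ± 0.548, 11.5 ± 1.84 and 15.9 ± 1.09 CPM in wild type (SD, n = 2). With a limit of 3 counts per library, these genes were at least 246-fold, 81.2-fold, 116-fold and 161-fold lower in heterozygous than in wild type. Xist, which is transcribed from the inactive X chromosome of female cells, was present in every library, at 659 ± 6.99 CPM in wild type, 1076 ± 6.02 in heterozygous and 652 ± 2.00 in knockout (SD, n = 2). Unless its reads stem from the overlapping antisense gene, this level goes against cultures of male cells alone in wild type and knockout too. Xist was 1.63-fold higher in heterozygous than in wild type (edgeR, adjusted p = 1.26e-27). The list of X-inactivation and Y-linked genes had 4 of 5 members lower in heterozygous than in wild type (camera, adjusted p = 0.000807, adjusted p = 0.192 with an estimated correlation). In knockout against wild type 2 of the 5, Ddx3y and Eif2s3y, rose, by 0.35 and 0.38 log2 (camera for the list, adjusted p = 0.204).

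**Figure D1:**
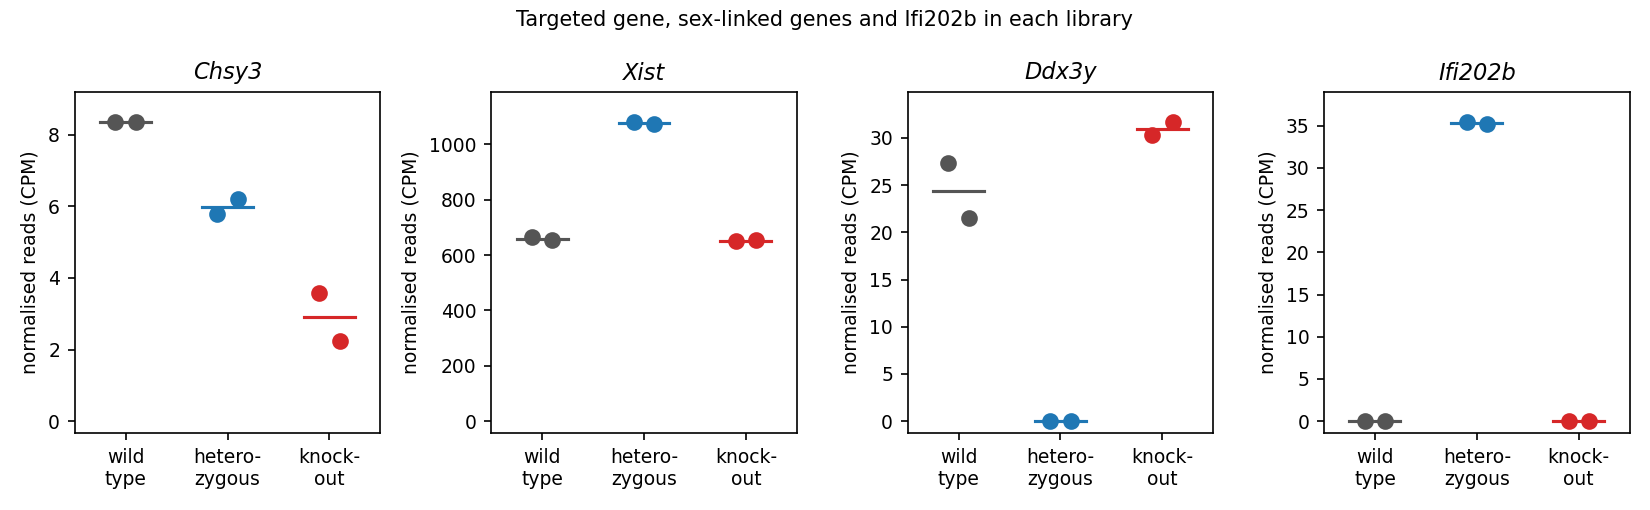
Normalised reads (CPM, linear axes from 0) of Chsy3, Xist, Ddx3y and Ifi202b in each library, with points for the 2 libraries of a genotype and bars for their mean. Chsy3 is highest in wild type and lowest in knockout, the heterozygous libraries have 0 counts of Ddx3y and the highest Xist, and they are the only libraries with reads of Ifi202b.

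The comparison of knockout with wild type asks what the loss of Chsy3 changes in these cultures. Collagen genes and genes of the actin cytoskeleton were lower in knockout by camera with a preset correlation. By the same test adipocyte markers, macrophage markers and genes of interferon response and antigen presentation were higher. None of these 6 lists passed with an estimated correlation (adjusted p = 0.213, 0.159, 0.159, 0.297, 0.159 and 0.213 in this order). The largest increase among the named genes was that of Sfrp2, a secreted Wnt antagonist, at 35.0-fold (log2 5.13 ± 0.06, SE, from 6.10 ± 0.0572 to 214 ± 1.55 CPM, SD, n = 2), and the largest decrease that of Slc4a10, a bicarbonate transporter, which fell by 5.70 on the log2 scale from 27.3 ± 1.73 CPM. In all, 6111 of 16061 genes passed the threshold (edgeR, adjusted p under the threshold of 0.05), 3082 higher and 3029 lower, and 491 of the higher and 605 of the lower changed at least 2-fold. Libraries of both groups did not overlap for 66.6% of genes, against 33.3% by chance.

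Further genes that rose in knockout were Lnx1, a ubiquitin ligase, at 19.3-fold, Sncg, which encodes gamma-synuclein, at 15.4-fold, the chloride channel regulator Clca3a1 at 13.1-fold, and Chrdl1, a secreted antagonist of bone morphogenetic proteins, at 11.5-fold. The endothelin receptor gene Ednrb rose 11.3-fold, the synaptotagmin gene Syt13 9.67-fold, Egfl6, which encodes a secreted matrix protein, 9.60-fold, Esm1, which encodes the proteoglycan endocan, 9.02-fold, and Agt, which encodes angiotensinogen, 8.14-fold. Genes that fell included Gdf10, a ligand related to bone morphogenetic proteins (log2 -4.39 ± 0.20, SE), Nkain4 (-4.06 ± 0.19), the matrix protein gene Smoc2 (-3.99 ± 0.10), the guidance cue Sema3d (-3.91 ± 0.10) and Piezo2, a stretch-activated channel (-3.88 ± 0.07). The remaining named decreases were those of Ano5 (-3.82 ± 0.18), Gjb2, which encodes connexin 26 (-3.54 ± 0.08), the desmosome gene Perp (-3.37 ± 0.15) and the cytokine Il33 (-3.31 ± 0.05). Adjusted p in edgeR was at most 5.32e-14 for these 20 genes, and the libraries of both groups did not overlap for any of them.

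Collagens fell in knockout. Of 26 tested collagen genes, 19 were lower, 2 higher and 5 not past the threshold (also 19 and 2 adjusted over the list alone), with a median log2 fold change of -0.69 (camera, adjusted p = 9.6e-09, adjusted p = 0.213 with an estimated correlation). Col4a1 and Col4a2, which form the main collagen of basement membranes, changed by -1.80 ± 0.03 and -1.59 ± 0.03 log2 (SE), and Col1a1, the main fibrillar collagen, by -0.97 ± 0.02, from 10593 ± 168 to 5414 ± 48.4 CPM (SD, n = 2). Col6a3 changed by -1.43 ± 0.03. The direction of the collagen median was the same under TMM, RLE and library totals.

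Other matrix genes went both ways. Of 27 proteoglycan core proteins, 7 were higher, with Prelp at 0.63 and Dcn, which encodes decorin, at 0.82 log2, and 13 were lower, with Cspg4 at -1.18 and Vcan, which encodes versican, at -0.80 (camera, adjusted p = 0.203). Matrix-degrading proteases split into 10 higher and 10 lower of 28, with Adam12 at -2.46, Adamts5 at 0.67, Mmp13 at 1.28 and Mmp2 at 0.66 log2 (camera, adjusted p = 0.9), and their median changed sign when libraries were scaled by their totals alone. Among 27 genes of chondroitin and dermatan sulfate synthesis, 10 fell and 2 rose, and the list as a whole did not pass the threshold (camera, adjusted p = 0.0932). The related synthase Chsy1 fell by 0.71 on the log2 scale, Chpf2 by 0.46 and Csgalnact1, which starts the chains, by 0.55. Genes of heparan sulfate synthesis and editing were lower, 9 of 16 against 1 higher (median log2 -0.29, camera, adjusted p = 0.00479, adjusted p = 0.213 with an estimated correlation). Glce was at -1.29 and Ext1 at -0.49 log2. Genes of glycosaminoglycan breakdown were higher, 10 of 17 against 2 lower (median log2 0.25, camera, adjusted p = 0.00687, adjusted p = 0.213 with an estimated correlation). The lysosomal enzyme genes Gusb and Hexa were at 0.65 and 0.57 log2.

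**Figure D2:**
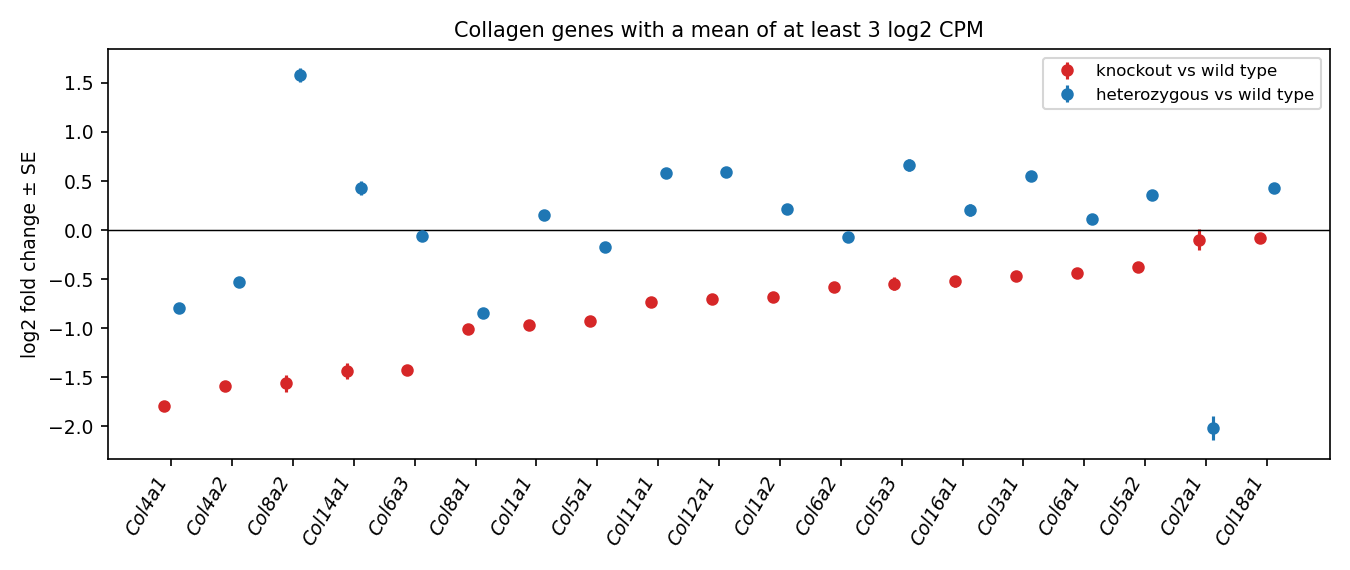
Log2 fold change against wild type (vertical axis, points with SE from edgeR, 2 libraries per genotype) of the 19 collagen genes with a mean of at least 3 log2 CPM, in knockout (red) and heterozygous (blue). The knockout value lies below the heterozygous value for 18 of the 19 genes, with Col4a1 lowest in knockout at -1.80.

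Genes of the contractile cytoskeleton fell. In the list of actin cytoskeleton and focal adhesion 27 of 42 were lower and 6 higher (median log2 -0.26, camera, adjusted p = 5.36e-05, adjusted p = 0.159 with an estimated correlation). Flnc, which encodes a filamin of muscle, was at -0.82 log2 and the LIM-domain gene Fhl1 at -1.33. Smooth muscle and myofibroblast markers were lower in 11 of 16 and higher in 2 (median log2 -0.48, camera, adjusted p = 0.000948, adjusted p = 0.193 with an estimated correlation). Tagln was at -1.04 and Acta2, which encodes smooth muscle actin, at -0.73 log2. TGF-beta targets and ligands were lower in 16 of 25 and higher in 4 (median log2 -0.30, camera, adjusted p = 0.000988, adjusted p = 0.265 with an estimated correlation). Thbs1 was at -0.69 and Fbn1, which encodes fibrillin, at -0.90 log2. The YAP/TAZ targets Cyr61 and Ctgf fell by 0.95 and 0.84 on the log2 scale, while their list went both ways, with 8 higher and 11 lower of 22 (camera, adjusted p = 0.191).

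Adipocyte markers and genes of immune cells rose. Whether the reads of adipocyte markers stem from fat cells was not tested in any comparison. Of 10 adipocyte markers, 8 were higher and 0 lower (also 9 and 0 adjusted over the list alone), with a median log2 fold change of 1.31 (camera, adjusted p = 2.09e-06, adjusted p = 0.159 with an estimated correlation). The lipase Lpl changed by 1.33 ± 0.03 log2 (SE), the lipid droplet gene Plin4 by 2.08 ± 0.14 and the regulator Cebpa by 0.87 ± 0.06. Macrophage markers were higher in 13 of 18 and lower in 1 (median log2 0.34, camera, adjusted p = 0.000156, adjusted p = 0.297 with an estimated correlation). The mannose receptor Mrc1 was at 1.28, Itgam at 0.61 and Cx3cr1, the gene that fell, at -2.25 log2. Interferon response genes were higher in 25 of 38 and lower in 1 (median log2 0.31, camera, adjusted p = 1.04e-05, adjusted p = 0.159 with an estimated correlation). Ifit2 was at 0.70 and Parp14 at 0.53 log2. Antigen presentation genes were higher in 8 of 11 and lower in 0 (median log2 0.66, camera, adjusted p = 0.000397, adjusted p = 0.213 with an estimated correlation). B2m was at 0.63 and H2-K1 at 1.04 log2. Inflammatory cytokines and NF-kB targets were higher in 19 of 29 and lower in 4 (median log2 0.39, camera, adjusted p = 0.000568, adjusted p = 0.193 with an estimated correlation). Among these the chemokines Cxcl12 and Ccl2 changed by 2.15 ± 0.02 and 1.23 ± 0.05 log2 (SE), and complement C3 by 1.07 ± 0.03.

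Metabolic lists showed small shifts in knockout. Cytosolic ribosomal proteins were lower in 43 of 59 and higher in 1 (median log2 -0.22, camera, adjusted p = 8.11e-08, adjusted p = 0.265 with an estimated correlation). Rpl3 was at -0.93 log2. Nuclear genes of oxidative phosphorylation were lower in 17 of 50 and higher in 0 (median log2 -0.10, camera, adjusted p = 0.00267, adjusted p = 0.309 with an estimated correlation). Genes of cholesterol synthesis were higher in 15 of 24 and lower in 2 (median log2 0.22, camera, adjusted p = 0.00165, adjusted p = 0.193 with an estimated correlation). Insig1 was at 0.77 log2. The unfolded protein and amino acid stress list was lower in 15 of 29 and higher in 5 (median log2 -0.11, camera, adjusted p = 0.0202, adjusted p = 0.213 with an estimated correlation), and its members with the smallest p-values, Phgdh, Psat1, Slc7a11 and Shmt2, are enzymes or transporters of serine, glycine and cystine. That call was lost without wild-type library 1 (camera, adjusted p = 0.0515), in a range of 0.00962 to 0.0515 over 14 alternatives with the preset correlation.

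The other lists did not pass the threshold in knockout against wild type. Nucleus pulposus and notochord markers had 4 members higher and 6 lower of 14, with Lgals3 at 1.55 and Krt19 at -2.55 log2 (camera, adjusted p = 0.625). Fibroblast and annulus fibrosus markers had 7 higher and 12 lower of 22, with Postn, which encodes periostin, at -1.04 and Thy1 at -1.16 (camera, adjusted p = 0.191). Chondrocyte markers had 3 higher and 1 lower of 16, with Comp at 1.55 and Sox9 at 0.51 (adjusted p = 0.521), and osteoblast and hypertrophy markers 6 and 3 of 13 (adjusted p = 0.384). Cell cycle genes had 9 higher and 5 lower of 45 (camera, adjusted p = 0.528), and p53 targets and CDK inhibitors 6 and 7 of 26 (adjusted p = 0.848). Wnt pathway genes had 8 higher and 9 lower of 28 (adjusted p = 0.655), BMP targets and regulators 4 and 10 of 22 (adjusted p = 0.139), hypoxia and glycolysis 7 and 15 of 31 (adjusted p = 0.135), and immediate early genes 4 and 10 of 23 (adjusted p = 0.29). Mitochondrially encoded genes had 2 higher and 1 lower of 13 (camera, adjusted p = 0.519). Among markers of other cells, osteoclast markers had 3 higher and 0 lower of 7 (adjusted p = 0.126), endothelial markers 4 and 3 of 10 (adjusted p = 0.525), pericyte markers 3 and 4 of 8 (adjusted p = 0.789), skeletal muscle markers 0 and 1 of 5 (adjusted p = 0.632) and epithelial markers 0 and 2 of 5 (adjusted p = 0.135). Neuron and Schwann cell markers had 5 lower and 1 higher of 12, with the Schwann cell regulator Sox10 at 1.41 ± 0.791 CPM in wild type and 0.0293 ± 0.0415 in knockout (SD, n = 2; camera, adjusted p = 0.0624), and this list passed the threshold without heterozygous library 1 or 2 or knockout library 1 (adjusted p = 0.0276, 0.0277 and 0.0279). It also passed with no filter on low counts, in the fit of only the 4 libraries compared and, chosen after the data were seen, with library totals alone (adjusted p = 0.0172, 0.0305 and 0.0441), so in 6 of 14 alternatives, with a range from 0.0172 to 0.991. In every comparison, a list whose median, mean and camera direction differed in sign was among those not past the threshold.

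**Figure D3:**
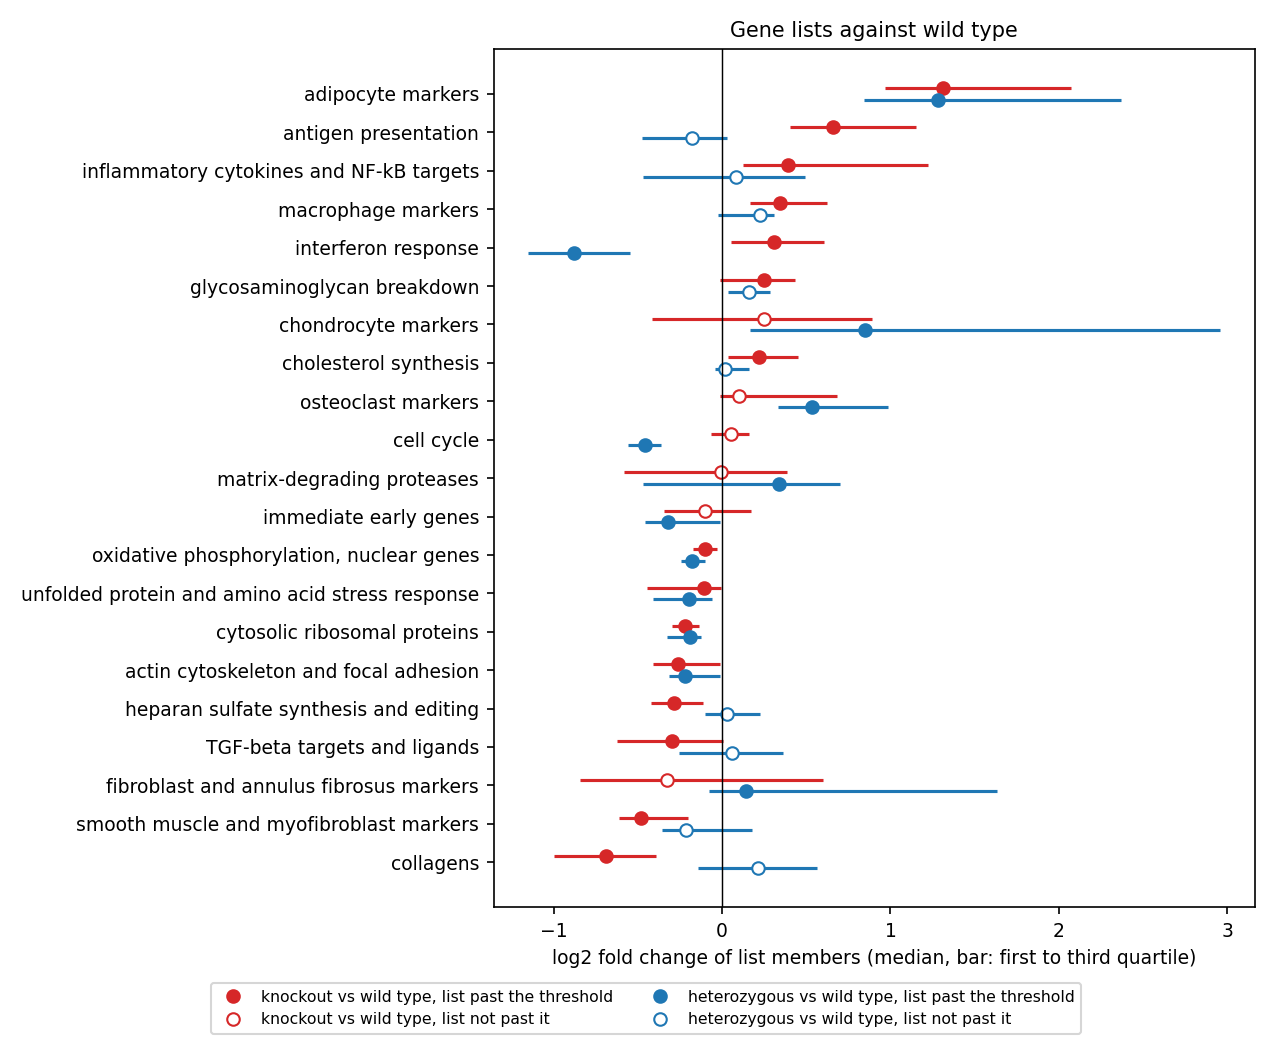
Median log2 fold change (horizontal axis) of the members of 21 gene lists against wild type in knockout (red) and heterozygous (blue), with lines from the first to the third quartile of members and filled points for lists past the camera threshold with a preset correlation, 15 in knockout and 12 in heterozygous. Interferon genes are higher in knockout and lower in heterozygous, adipocyte markers are higher in both, and the small medians of proteases in knockout and of cholesterol and heparan sulfate genes in heterozygous change sign when libraries are scaled by their totals alone.

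The comparison of heterozygous with wild type asks what the loss of a single allele changes. Interferon response and cell cycle genes were lower in heterozygous, and fibroblast, chondrocyte and adipocyte markers were higher, by camera with a preset correlation. None of these 5 lists passed with an estimated correlation (adjusted p = 0.0676, 0.122, 0.192, 0.192 and 0.122 in this order). Ifi202b (chromosome 1, 173962569 to 173982844, GRCm38), an interferon-inducible gene of the Ifi200 cluster, had 0 counts in both wild-type libraries and 1022 and 1118 in the heterozygous libraries, at least 400.1-fold higher with a limit of 3 counts per library. Its near-identical neighbours make its count uncertain. These libraries are also those with no reads of Y-linked genes, so sex-linked and genotype differences are joined in this comparison. In all, 6248 of 16061 genes passed the threshold (edgeR, adjusted p under the threshold of 0.05), 3076 higher and 3172 lower, 649 and 493 of them at least 2-fold. With libraries scaled by their totals alone 2628 were higher and 3762 lower, and 6005 passed in a fit without genes on the X and Y chromosomes, both settings chosen after the data were seen. Libraries of both groups did not overlap for 67.0% of genes, against 33.3% by chance.

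Matrix and secreted protein genes led the increases. Egfl6 rose 56.5-fold (log2 5.82 ± 0.23, SE), Thbs4, a thrombospondin of tendon matrix, 46.8-fold (log2 5.55 ± 0.12), Chrdl1 28.8-fold and Sfrp2 24.7-fold. Lnx1 rose 17.2-fold, Clca3a1 13.7-fold, the adaptor gene Sorbs2 10.1-fold and Gprin3 9.94-fold. Besides the Y-linked Ddx3y, Eif2s3y and Kdm5d, the named decreases were those of Gjb2 (log2 -6.29 ± 0.12, SE, from 125 ± 0.954 to 1.62 ± 0.555 CPM, SD, n = 2), Slc4a10 (-6.22 ± 0.24), Sema3d (-4.78 ± 0.12) and Crct1 (-4.65 ± 0.21). Slc4a4, another bicarbonate transporter, fell by 4.22 on the log2 scale, Smoc2 by 4.16 and the transcription factor gene Zic2 by 4.03. Adjusted p in edgeR was at most 5.32e-16 for these genes. Egfl6 and Chrdl1 lie on the X chromosome.

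Interferon response genes were lower in 36 of 38 and higher in 0 (also 37 and 0 adjusted over the list alone), with a median log2 fold change of -0.88 (camera, adjusted p = 9.06e-18, adjusted p = 0.0676 with an estimated correlation). Isg15, a ubiquitin-like modifier, changed by -2.03 ± 0.07 log2 (SE), Oasl2 by -1.09 ± 0.04 and Bst2 by -0.88 ± 0.04. Cell cycle genes were lower in 43 of 45 and higher in 0 (median log2 -0.46, camera, adjusted p = 1.43e-14, adjusted p = 0.122 with an estimated correlation). The spindle gene Tpx2 was at -0.69, Prc1 at -0.63 and Top2a, which encodes topoisomerase II, at -0.39 log2. Immediate early genes were lower in 12 of 23 and higher in 4 (median log2 -0.32, camera, adjusted p = 0.00836, adjusted p = 0.192 with an estimated correlation). Egr1 was at -1.40 and Myc at -0.62 log2. These lists moved in the libraries without Y-linked reads, in which the macrophage genes Lyz2 and Mrc1 were at 8845 ± 0.5 and 1853 ± 16.5 CPM, against 7211 ± 125 and 751 ± 0.679 in wild type (SD, n = 2). Macrophage markers as a list had 10 of 18 higher and 3 lower (camera, adjusted p = 0.0538), and this list passed the threshold without wild-type library 1, with RLE size factors and with no filter on low counts (adjusted p = 0.0293, 0.0483 and 0.0311), so in 3 of 14 alternatives, with a range from 0.0293 to 0.0960.

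Fibroblast and chondrocyte markers were higher in the heterozygous libraries, whereas osteoblast and hypertrophy markers, with 5 higher and 3 lower of 13, and nucleus pulposus and notochord markers, with 6 and 4 of 14, did not pass the threshold (camera, adjusted p = 0.588 and 0.477). Fibroblast and annulus fibrosus markers rose in 14 of 22 and fell in 3 (median log2 0.14, camera, adjusted p = 0.00764, adjusted p = 0.192 with an estimated correlation). Postn was at 1.57, Pdgfra at 1.65 and Cd34 at 2.61 log2. Chondrocyte markers rose in 9 of 16 and fell in 1 (median log2 0.85, camera, adjusted p = 0.00764, adjusted p = 0.192 with an estimated correlation). Comp, a cartilage matrix protein gene, changed by 3.14 ± 0.05 log2 (SE) and the cartilage regulator Sox9 by 1.85 ± 0.08, from 16.0 ± 1.05 to 57.5 ± 0.997 CPM (SD, n = 2), while Col2a1, the main cartilage collagen, changed by -2.01 ± 0.12. Adipocyte markers rose in 10 of 10 (median log2 1.28, camera, adjusted p = 2.2e-07, adjusted p = 0.122 with an estimated correlation). Lpl was at 0.87 and Plin4 at 1.70 log2. Osteoclast markers rose in 5 of 7 and fell in 0 (median log2 0.53, camera, adjusted p = 0.00135, adjusted p = 0.316 with an estimated correlation). Itgb3 was at 0.53 log2. Matrix-degrading proteases rose in 16 of 28 and fell in 7 (median log2 0.34, camera, adjusted p = 0.0248, adjusted p = 0.212 with an estimated correlation). Adamts5 was at 1.204 and Mmp2 at 1.08 log2. The protease call was lost without heterozygous library 2 or knockout library 1 or 2 and in the fit of only the 4 libraries compared (camera, adjusted p = 0.0539, 0.0514, 0.0510 and 0.0550), so in 4 of 14 alternatives, with a range from 0.00784 to 0.0550.

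Collagens went both ways in heterozygous against wild type, with 15 higher and 8 lower of 26 (median log2 0.21, camera, adjusted p = 0.139). Col3a1 and Col12a1 rose by 0.55 and 0.59 log2, and Col4a1 and Col8a1 fell by 0.80 and 0.85. Among 27 proteoglycan core proteins 13 rose, with fibromodulin (Fmod) at 1.43 and Dcn at 1.58, and 6 fell (camera, adjusted p = 0.0679). That list passed the threshold with no filter or a stricter filter on low counts (adjusted p = 0.0366 and 0.0380), with a range of 0.0366 to 0.135 over 14 alternatives. Of 27 genes of chondroitin and dermatan sulfate synthesis 9 rose and 10 fell, with Chpf2 at -1.12 and Csgalnact1 at 0.58 (camera, adjusted p = 0.961). Actin cytoskeleton and focal adhesion genes were lower in 28 of 42 and higher in 2 (median log2 -0.22, camera, adjusted p = 5.14e-05, adjusted p = 0.122 with an estimated correlation). Fhl1 was at -1.996 log2. Cytosolic ribosomal proteins were lower in 41 of 59 and higher in 1 (median log2 -0.19, camera, adjusted p = 6.91e-08, adjusted p = 0.316 with an estimated correlation), and nuclear genes of oxidative phosphorylation in 27 of 50 and 0 (median log2 -0.18, camera, adjusted p = 3.98e-06, adjusted p = 0.212 with an estimated correlation). The unfolded protein and amino acid stress list was lower in 19 of 29 and higher in 3 (median log2 -0.20, camera, adjusted p = 0.000213, adjusted p = 0.139 with an estimated correlation). The cystine transporter Slc7a11 was at -2.33 log2. Epithelial markers had 2 lower and 0 higher of 5, among them Perp at -3.74 (camera, adjusted p = 0.0606), and passed the threshold without wild-type library 1 or heterozygous library 1 and with no filter on low counts (adjusted p = 0.0293, 0.0139 and 0.0207), so in 3 of 12 alternatives, with a range from 0.0139 to 0.140.

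The comparison of knockout with heterozygous sets the loss of both alleles against that of a single allele. It also sets libraries with Y-linked reads against libraries without them, so sex-linked and genotype differences are joined here too. Interferon response genes were higher in knockout in 38 of 38 (median log2 1.31, camera, adjusted p = 6.36e-23, adjusted p = 0.0464 with an estimated correlation), the sole list in any comparison past the threshold with an estimated correlation. Cell cycle genes were higher in 42 of 45 and lower in 1 (median log2 0.50, camera, adjusted p = 9.19e-15, adjusted p = 0.146 with an estimated correlation). Collagens were lower in 20 of 26 and higher in 2 (median log2 -0.95, camera, adjusted p = 1.71e-10, adjusted p = 0.153 with an estimated correlation), with Col1a1 at -1.12 ± 0.02 and Col12a1 at -1.29 ± 0.02 log2 (SE). In all, 5951 genes passed the threshold (edgeR, adjusted p under the threshold of 0.05), 3070 higher and 2881 lower, and 419 of the higher and 592 of the lower changed at least 2-fold. Of the genes past the threshold 51.6% were higher, a share that became 64.7% when libraries were scaled by their totals alone, a setting chosen after the data were seen, and 41.4% among genes changed at least 2-fold. Libraries of both groups did not overlap for 65.7% of genes, against 33.3% by chance.

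Among the named genes, the Y-linked Ddx3y, Eif2s3y and Kdm5d were at least 312-fold, 209-fold and 119-fold higher in knockout, and Ifi202b, with 0 counts in knockout, was at least 394-fold lower. Sfrp4, a Wnt antagonist, rose 6.80-fold and Crct1 7.85-fold. Thbs4 fell by 6.63 on the log2 scale, from 103 ± 3.64 to 1.04 ± 0.65 CPM (SD, n = 2), the somite transcription factor Meox1 by 4.71, Eln, which encodes elastin, by 4.34, and C1qtnf3 by 3.88. Adjusted p in edgeR was at most 4.05e-14 for these genes.

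Fibroblast markers, proteoglycans and proteases were among the lists lower in knockout than in heterozygous, whereas osteoblast and hypertrophy markers, with 4 higher and 3 lower of 13, did not pass the threshold (camera, adjusted p = 0.871). Fibroblast and annulus fibrosus markers were lower in 16 of 22 and higher in 4 (median log2 -0.75, camera, adjusted p = 7.55e-06, adjusted p = 0.146 with an estimated correlation). Postn was at -2.61 log2. Proteoglycan core proteins were lower in 16 of 27 and higher in 4 (median log2 -0.50, camera, adjusted p = 0.000124, adjusted p = 0.153 with an estimated correlation). Fmod was at -1.45 and Bgn, which encodes biglycan, at -0.78 log2. Proteases were lower in 19 of 28 and higher in 2 (median log2 -0.31, camera, adjusted p = 6.9e-05, adjusted p = 0.146 with an estimated correlation). Adamts5 was at -0.53 log2. TGF-beta targets and ligands were lower in 17 of 25 and higher in 4 (median log2 -0.36, camera, adjusted p = 0.000474, adjusted p = 0.155 with an estimated correlation), and Wnt pathway genes in 15 of 28 and 4 (median log2 -0.55, camera, adjusted p = 0.00388, adjusted p = 0.155 with an estimated correlation). Sfrp1 was at -1.30 log2. Chondrocyte markers were lower in 6 of 16 and higher in 2 (median log2 -1.05, camera, adjusted p = 0.00929, adjusted p = 0.153 with an estimated correlation). Sox9 was at -1.34 and Comp at -1.59 log2. Smooth muscle and myofibroblast markers were lower in 11 of 16 and higher in 2 (median log2 -0.25, camera, adjusted p = 0.00991, adjusted p = 0.153 with an estimated correlation), and pericyte markers in 6 of 8 and 1 (median log2 -0.43, camera, adjusted p = 0.0104, adjusted p = 0.155 with an estimated correlation). Genes of heparan sulfate synthesis were lower in 8 of 16 and higher in 2 (median log2 -0.27, camera, adjusted p = 0.00451, adjusted p = 0.153 with an estimated correlation), and hypoxia and glycolysis genes in 17 of 31 and 5 (median log2 -0.13, camera, adjusted p = 0.00388, adjusted p = 0.155 with an estimated correlation). The glucose transporter Slc2a1 was at -0.62 log2. Neuron and Schwann cell markers were lower in 7 of 12 (median log2 -1.54, camera, adjusted p = 0.0226, adjusted p = 0.155 with an estimated correlation), with Sox10 at 3.14 ± 0.66 CPM in heterozygous and 0.0293 ± 0.0415 in knockout (SD, n = 2), and this call was lost under the stricter filter on low counts (adjusted p = 0.748), the highest in a range from 0.00539 over 14 alternatives.

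Immune lists were higher in knockout than in heterozygous. Antigen presentation genes were higher in 8 of 11 (median log2 0.84, camera, adjusted p = 2.58e-05, adjusted p = 0.153 with an estimated correlation), with H2-T23 at 1.01 log2, and inflammatory cytokines and NF-kB targets in 13 of 29 with 5 lower (median log2 0.31, camera, adjusted p = 0.00993, adjusted p = 0.153 with an estimated correlation). Ccl2 was at 1.23 and Vcam1 at -1.13 log2. Macrophage markers were higher in 12 of 18 and lower in 3 (median log2 0.20, camera, adjusted p = 0.0249, adjusted p = 0.406 with an estimated correlation). Fcer1g was at 0.46, Itgam at 0.30 and Lyz2, among those that fell, at -0.33 log2. Genes of cholesterol synthesis were higher in 12 of 24 and lower in 1 (median log2 0.16, camera, adjusted p = 0.00129, adjusted p = 0.153 with an estimated correlation). Nuclear genes of oxidative phosphorylation were higher in 11 of 50 (median log2 0.08, camera, adjusted p = 0.0226, adjusted p = 0.344 with an estimated correlation), a call lost without heterozygous library 1 or knockout library 2 (adjusted p = 0.0566 and 0.0548), with a range of 0.00281 to 0.0566 over 14 alternatives. BMP targets and regulators were lower in 12 of 22 and higher in 4 (median log2 -0.29, camera, adjusted p = 0.0487, adjusted p = 0.181 with an estimated correlation), a call lost without wild-type library 1 or 2, heterozygous library 2 or knockout library 1 (adjusted p = 0.0564, 0.0569, 0.0577 and 0.0691). It was also lost with RLE size factors, the stricter filter on low counts, the fit of only the 4 libraries compared and, chosen after the data were seen, without X and Y chromosome genes (adjusted p = 0.0557, 0.0529, 0.118 and 0.0836), so in 8 of 14 alternatives, with a range from 0.0188 to 0.118. The X-inactivation and Y-linked list had 4 members higher and 1, Xist, lower (camera, adjusted p = 0.000612, adjusted p = 0.153 with an estimated correlation). Adipocyte markers had 4 higher and 1 lower of 10 (camera, adjusted p = 0.312), and passed the threshold with the stricter filter on low counts (adjusted p = 0.0396, in a range up to 0.465 over 14 alternatives).

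Changes in heterozygous and knockout against wild type were correlated across genes. Pearson's r of the log2 fold changes was 0.565 and Spearman's rho 0.473 over 16061 genes, which are not independent replicates. The mean r was 0.499 and the highest 0.520 in 20 simulations with unchanged groups. There all 6 libraries were drawn anew from the wild-type means, and both comparisons shared the simulated wild-type libraries. The covariance was 0.412 against 0.0419 in the simulations, a difference of 0.370. The log2 fold changes had the same sign for 68.1% of genes, against 66.6% in the simulations. Genes past the threshold in both comparisons were higher in both in 1614 cases, lower in both in 1594 and opposite in 561, where independent lists of these lengths would share 590, 598 and 1189. Each part of a split wild-type group would hold 1 library, so the controls were not split, and part of the excess may come from the shared controls. Among the named genes 9 were shared by both comparisons, all in the same direction, namely Sfrp2, Lnx1, Clca3a1, Chrdl1, Egfl6, Slc4a10, Smoc2, Sema3d and Gjb2.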

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

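Scaling by library totals alone and the fit without X and Y chromosome genes were chosen after the data were seen, and the other alternatives before. Each of the 50 changes of genes selected by the naming rule kept its direction and stayed past the threshold in all settings run, with 10 of them not tested when X and Y chromosome genes were left out. Counts of genes past the threshold stayed within 1.5 times, from 5064 to 6261 in knockout against wild type, 5186 to 6228 in heterozygous against wild type and 4823 to 6057 in knockout against heterozygous when a library was left out, and 5302, 5334 and 5047 with DESeq2. A lone library left in a group is then assumed to vary like the other groups. The minimum of a 2-fold change lowered the counts to 1096, 1142 and 1011 by its own construction.

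Chsy3 in heterozygous against wild type kept its direction but did not pass the threshold with DESeq2, at -0.47 log2, nor without a wild-type or heterozygous library, with a range of -0.53 to -0.43 over the libraries left out, and the cause was not tested beyond the smaller number of samples. Its log2 fold change in knockout against wild type stayed between -1.90 and -1.22. The correlation between the comparisons with wild type ranged from 0.48 to 0.65 when a library was left out, and it has no value for a fit of 4 libraries. With an estimated correlation the lists past the camera threshold numbered 0, 0 and 1 for knockout against wild type, heterozygous against wild type and knockout against heterozygous, in place of 15, 13 and 21. This loss does not measure correlation between genes alone, since that form tests on the 3 residual degrees of freedom. For the interferon list in heterozygous against wild type, unadjusted camera p went from 2.45e-19 to 0.00183. Its estimated correlation was -0.00298, below the preset 0.01. Camera was not run with DESeq2, which gives no log2 CPM.

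Replicate numbers do not pair the libraries, since deviations of same-numbered libraries correlated at -0.02, 0.01 and 0.02. With the replicate block the counts were 6080, 6222 and 5913, and the block changed no call of a named gene, of Chsy3 or of a list. In the simulated knockout comparison 18 of 50 genes changed 1.2-fold were called. All of them were among the 44 with a mean of at least 20 counts, so small simulated changes were missed above that level too. The simulation changed far fewer genes than the 6111 past the threshold in the data. Its Benjamini-Hochberg adjustment is then stricter, so these shares do not measure the sensitivity of the real comparison.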

Other observations

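All tests below address patterns that had already been seen in these data. The rules for the tests of depth, of Xist, of macrophage markers and of fibroblast markers were written after the values they rest on were seen. Those for the other tests were written before their own outcome was seen. The set of Ifi200 family genes left out of the test around Ifi202b was widened after a first result, with the same reading. Genes singled out in the next paragraph were chosen after their values were seen.

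Neighbours of Ifi202b in the Ifi200 cluster on chromosome 1 went the other way from Ifi202b in the heterozygous libraries. Mndal fell by 1.82 ± 0.08 on the log2 scale (SE, edgeR, adjusted p = 1.76e-22), from 43.7 ± 0.94 to 12.4 ± 0.179 CPM (SD, n = 2), Ifi204 by 1.12, Ifi203 by 1.03 and Mnda by 1.14. In knockout against wild type the same genes were at 0.34, 0.49, 0.65 and 0.22 log2, all past the threshold and higher. Foxc2, a transcription factor gene, fell by 3.11 in heterozygous and 1.85 in knockout, from 64.6 ± 1.30 CPM in wild type (SD, n = 2), Zic1 by 2.27 and 2.01, and Foxc1 by 0.88 and 0.84, whereas Tbx18 rose by 0.91 in knockout.

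The heterozygous libraries held no reads of 4 Y-linked genes, and they alone held reads of Ifi202b. Depth is argued against, since 3736 such reads were expected from the wild-type share and 0 were seen, and a loss of the Y chromosome with the share of female cells kept is argued against by Xist, which was at 1.63 times its wild-type level in heterozygous and 0.990 times in knockout. Heterozygous cultures without male cells, beside wild-type and knockout cultures of mixed sex, are a candidate explanation, given the 0 Y-linked reads and the higher Xist. Genes that escape X inactivation add little to it, and their rule set no minimum size. Their median log2 fold change was 0.0653, with 5 of 5 above 0 and 2 of 5, Kdm6a at 0.47 and Kdm5c at 0.12, past the threshold. Ddx3x, Eif2s3x and Pbdc1 lay between 0.057 and 0.0653 and did not pass (edgeR, adjusted p = 0.0582, 0.558 and 0.580). An interval of another mouse strain around Ifi202b, a gene that C57BL/6 mice express little, cannot be told apart from other causes. Ifi200 family genes and the interferon list were left out by symbol. AI607873 and Gm16340, close to Ifi202b, stayed in, at -0.98 and -1.07 log2, so the family may not be fully removed. The 90 placed genes kept within 5 Mb had a median absolute change of 0.28 log2. That is above the median of other windows (0.23) and below their 95th percentile (0.32). Loss of Chsy3 itself is argued against, since the knockout libraries held Ddx3y, Uty, Kdm5d and Eif2s3y at 31.0, 10.2, 11.8 and 20.7 CPM, against 24.4, 8.06, 11.5 and 15.9 in wild type, and 0 counts of Ifi202b, as wild type did, while a difference in the sex of the animals stays open.

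Collagens were lower in knockout than in wild type. A larger share of macrophage-like cells as the whole cause is argued against, since the 16 macrophage markers over 100 CPM had log2 fold changes with an interquartile range of 0.443, and 4 of them, among them Lyz2 at -0.04 and Cx3cr1 at -2.25, did not rise beyond 0.1. Fibroblast markers do not decide on a smaller share of fibroblast-like cells. Of 22 markers, 7 rose past the threshold by at least 0.3 log2, but 12 fell (median log2 -0.33), and the rule counted the risers alone. TMM scaling as the cause is argued against by the collagen median, at -0.69 under TMM and -0.67 in the setting nearest to 0. TMM factors of the wild-type and knockout libraries lay between 1.004 and 1.02, so these settings differed little. A scaling error common to all settings was not tested. A change in the kind of fibroblast or macrophage that grew out of the tissue was not tested. Since such a change in the mix of cells was left open, and meningeal genes also fell, an effect of the knockout genotype on collagen expression stays open and untested.

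Genes known from arachnoid and meningeal cells, such as Slc4a10 and Gjb2, were among those most reduced in heterozygous and knockout. A list of 20 other meningeal markers, of which 13 were tested and 1, Cdh1, is also in the epithelial list, had a median of -2.27 log2 in heterozygous. With 8 lower and 0 higher past the threshold, it met the rule set for fewer meningeal cells there. The fall was uneven, with Foxc2 at -3.11 and Foxc1 at -0.88 log2. Aldh1a2 at 0.14 and Tbx18 at -0.06 log2 did not pass the threshold (edgeR, adjusted p = 0.135 and 0.775). The most abundant members in wild type were Foxc1 at 107, Zic1 at 77.4 and Foxc2 at 64.6 CPM. In knockout the median was -1.73, with 7 lower and 2, Aldh1a2 and Tbx18, higher past the threshold. That median is the value of Slc47a1, at 0.456 CPM in wild type and 0.136 in knockout and not past the threshold (edgeR, adjusted p = 0.167). Next to it in rank were the more abundant Foxc2 at -1.85 and Foxc1 at -0.84 log2. Fewer meningeal cells thus cannot be told apart from a change of single genes in knockout, nor, given the uneven fall, in heterozygous. A passenger interval flanking Chsy3 as the whole cause is argued against for the 4 genes named as reduced in both comparisons. Of these, 0 lie within 10 Mb of Chsy3. The share of the 110 genes there that changed at least 2-fold, 9.09%, decides nothing. It lay between the median (6.36%) and the 95th percentile (11.8%) of other windows. Piezo2 lies there, and the naming rule listed it in knockout alone. Its log2 fold change was -3.88 in knockout and -2.50 in heterozygous, so the interval stays open for Piezo2. An effect of the Chsy3 genotype itself stays open, since no label says whether the cultures of each genotype were dissected alike.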
